A study of Caenorhabditis elegans with 2 samples.

How the data were processed

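ChIP-seq with an antibody against GFP was done on whole young adult C. elegans (65 h) whose egrh-3 gene carried a TY1, eGFP and 3xFLAG tag at its own locus, and chromatin was sonicated to 200 to 800 bp, per the labels. The samples formed 1 group of 2 biological replicates, numbered as in the labels. The series held 4 series-level peak lists and 2 lists for each replicate, all on ce11 per the file headers and names. The aligner, the peak caller and their versions are not given in the sources used here. A control library was named for the experiment, per the labels, and its data were not used here. Peak lists from an untagged strain were not analysed here either, so background enrichment was not measured.

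Each list gives one row per peak with an interval, a summit and the authors' values. The signal of a peak is the authors' deposited measure of its strength against control, with no stated scaling, so it was used to rank and describe peaks, and signals of different lists were not taken to share a scale. The deposited −log10 values are a q-value and, in the ranked lists, the global irreproducible discovery rate (IDR). The global IDR of a peak is the estimated share of irreproducible peaks among all peaks of its rank or better. The deposited score is a whole number up to 1000 that follows the IDR, and its lowest value of 830 in each thresholded list corresponds to a global IDR of 0.01. The authors' IDR filter was applied before deposit. The conservative thresholded list was the main set, fixed before the data were examined. Its peaks were all found in the ranked list whose paired intervals matched the replicates' own ranked lists in 72.8% and 70.6% of 26742 rows. The other ranked list matched neither. Of 2419 ranked regions past the same score, 201 were absent from the conservative list. The thresholded lists name an additional input file that the ranked lists do not, per the file headers, and its role is not stated there.

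Summits that shared an interval were kept as separate peaks, so the conservative list held 95 more peaks than distinct intervals. Only nuclear peaks entered the comparisons with the genome. The reference was the WBcel235 assembly with the Ensembl gene annotation for it, and all peaks lay within its chromosome ends. A promoter was the stretch from 1000 bp upstream to 200 bp downstream of an annotated 5' end of a protein-coding transcript. Each summit was given the first fitting class of promoter, 5' UTR, coding exon, 3' UTR, intron, exon of a noncoding gene and intergenic, so a promoter summit can also lie in a neighbouring gene. Class and chromosome shares were compared with shares of bases by two-sided exact binomial tests, weighted by chromosome for the classes. The 39 gene lists were tested by two-sided Fisher's exact tests of promoter summits against all 19973 nuclear protein-coding genes. Motifs were searched on both strands within 50 bp of summits and in windows centred 300 bp to each side by exact McNemar tests. Intervals of motif ratios came from the exact binomial interval of the summit windows among all windows with the motif, and those of stratified odds ratios from the Mantel-Haenszel estimate with its normal approximation. Benjamini-Hochberg adjustment ran over 7 classes, 6 chromosomes, 39 lists, 5 RNA classes or 2080 6-mers. Replicate signals were read from each replicate's own ranked list at the conservative summit, taking the strongest region that covered it.

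Genes were named by a rule set before the data were examined. It took the EGR list in full, the nearest gene of the 15 strongest peaks with a promoter gene (both genes of a divergent pair within 200 bp), the 3 strongest bound members of each list past the threshold, and the strongest bound member of other lists where an example was needed. Genes named for a summit inside the gene, the further summits at mab-10, lin-29 and egrh-1, and the genes found at another gene's promoter summit were chosen after their values were seen. With 2 replicates and 1 group, no test between conditions could be made, and the difference between the replicates' values is the only measure of their spread. Annotation classes, chromosome shares, the 39 lists for promoter summits, GTGGGYG, noncoding RNA genes and col genes were therefore also computed from each replicate's own list, while the other sequence patterns, the 6-mers and the list tests of summits inside genes were not. Alternatives fixed before the data were examined were the larger list, a stricter IDR, the stronger part of the list by signal, other promoter windows, all gene 5' ends, peak midpoints, the nearest gene only, a background of genes with a ranked region, and other overlap and motif settings. Alternatives chosen after seeing the data were an IDR under 0.001, promoter windows without coding exons, and summits inside genes. The comparisons of GC content and of col genes were also chosen then.

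The tests were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. They were tested on simulated data. Over the 19973 genes, lists bound at 8 times the rate of other genes were found in 100% of 300 tests, lists bound at 4 times in 83.7% of 300, and lists bound at the common rate were called in 0.522% of 2300. Higher rates were planted in longer lists only, so the shares found do not cover short lists such as the EGR and heterochronic genes. Genes were drawn independently there, whereas real genes can share a summit. Over 2000 random positions, the promoter test fell below 0.05 in 2 of 100 draws, and a motif planted in 5% of windows was found in 10 of 10 draws. Random positions are not richer in GC than their flanks, whereas the real summits had a mean of 56.0% GC against 39.5% in the flanks. The motif draws therefore do not cover the motif test in that setting.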

Results

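Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map the genomic sites occupied by EGRH-3, a zinc finger protein of the EGR (early growth response) family, in Caenorhabditis elegans. The worms carried eGFP at the endogenous egrh-3 gene on chromosome IV, inserted by CRISPR, and an antibody against GFP pulled down the fusion protein with its DNA. Whole young adults were collected at 65 h after synchronisation by larval starvation. The series held 1 group of 2 biological replicates, so the data answered where the tagged protein was found and how far the replicates agreed, and they held no comparison between conditions. The files were peak lists without read counts, so the sequencing depth behind each replicate is unknown. Positions are given on ce11, the assembly also named WBcel235. Intervals are 95% intervals, exact (Clopper-Pearson) for shares and exact conditional for the odds ratios of gene lists. They cover counting error over peaks or genes, which are not independent replicates. A gene with a summit in its promoter window is called bound here as a shorthand. Lists from untagged worms were not analysed here, so binding could not be told from background enrichment at any summit.

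The conservative list, which rested on both replicates, held 2218 peaks, of which 2194 lay on the nuclear chromosomes and 24 on mitochondrial DNA. The nuclear peaks had a median width of 400 bp and covered 0.688% of the nuclear genome. Their signal value, a measure of peak strength given by the authors for each peak, had a median of 140 and ran from 10.1 to 5852. A larger deposited list held 3278 peaks, 1.48 times as many, and 2076 of the conservative peaks were in it with the same coordinates and summit.

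The replicates differed in length and overlapped in part. Replicate 1 gave 2868 peaks in its own list and replicate 2 gave 1463, a ratio of 1.96. Of the 1439 nuclear peaks of replicate 2, 1122 overlapped a peak of replicate 1 by at least 1 bp (78%, 95% interval 75.7 to 80.1), against 1.96% estimated for randomly placed peaks. In the other direction, 40.5% of the 2850 nuclear peaks of replicate 1 overlapped a peak of replicate 2. When the strongest 1439 peaks of each were compared, 56.8% of those of replicate 2 overlapped. Across the 2070 conservative peaks with a signal in both replicates, the ranks of the signals were correlated with a Spearman rho of 0.456. That correlation is across peaks, which are not independent replicates, and the list itself kept peaks that ranked alike in both. Without the IDR threshold, over 11452 ranked peaks with a signal in both replicates, rho was higher, at 0.573.

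The tagged gene and its partners were examined first. A peak stood upstream of egrh-3 itself (WBGene00044651, chromosome IV, 2680098 to 2688766, minus strand). Its interval ran from 2688956 to 2689261 with the summit at 2689117, 351 bp upstream of the 5' end, and its signal of 467 ranked 194 among the nuclear peaks. The same base lay in a coding exon of the upstream gene Y94H6A.5. The 41 bases from 2689097 to 2689137 read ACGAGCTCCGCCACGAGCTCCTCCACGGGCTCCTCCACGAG, and the GC content within 50 bp of the summit was 70.3%. The peak was in the lists of both replicates, with a signal of 396 in replicate 1 and 72.7 in replicate 2.

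A peak of similar strength stood upstream of mab-10 (WBGene00003107, chromosome II, 10528084 to 10534380, plus strand), which encodes the worm's NAB protein, a cofactor of EGR-type zinc fingers that acts with LIN-29 at the transition from larva to adult. Its summit at 10527757 was intergenic, 327 bp upstream, with a signal of 395 and rank 255. The GC content within 50 bp of that summit was 66.3%, and the signal was 325 in replicate 1 and 71.3 in replicate 2. The 41 bases from 10527737 to 10527777 read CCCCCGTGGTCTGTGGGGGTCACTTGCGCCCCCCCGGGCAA. A weaker peak, with a signal of 116, lay in a coding exon of mab-10 at 10531766. The thresholded list of replicate 1 held a summit there, at 10531810, and that of replicate 2 did not. A peak 903 bp upstream of egrh-2 (WBGene00043705, chromosome IV, 984384 to 990452), with its summit at 991355 and a signal of 95.1, was absent from the thresholded list of replicate 1, although the signals there in the replicates' ranked lists were 45.7 in replicate 1 and 46.9 in replicate 2. No conservative summit fell in the promoter window of lin-29 (WBGene00003015, chromosome II, 11917642 to 11935343) or egrh-1 (WBGene00007772, chromosome X, 14845937 to 14849217). An intron of lin-29 held a summit at 11929002 with a signal of 88.2, which was in neither replicate's own thresholded list. The larger list placed a summit of signal 98.6 at 14844866, 1071 bp upstream of egrh-1 and so just outside the window. Of the replicates' own thresholded lists, only that of replicate 1 held a summit there, at 14844864. In all, 3 of the 5 genes of this list had a promoter summit, against 4.86% of all 19973 protein-coding genes (odds ratio 29.4, 95% interval 3.37 to 353, adjusted p = 0.00519 by Fisher's exact test). With the list of replicate 1 alone the count was 2 of 5, the odds ratio 12.6 and the exact adjusted p 0.0809. The 3 conservative promoter summits had a median GC content of 66.3%. The median ratio of their replicate 1 to replicate 2 signals was 4.57. GC content was not taken into account in the test of this list.

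The strongest peaks with a promoter gene were assigned to genes of varied function. The 15 strongest had signals from 1005 to 2134, and each overlapped a peak in the list of replicate 1 and in that of replicate 2. The first stood 726 bp upstream of inx-18, a gap junction innexin (chromosome IV, summit 605629, signal 2134). It was followed by unk-1 (chromosome X, 8017422, signal 2069), ntl-2, a subunit of the CCR4-NOT complex (chromosome II, 4376964, signal 1691), Y66A7A.4 (chromosome III, 11611880, signal 1686) and grk-1, a kinase of G protein-coupled receptors (chromosome X, 9999724, signal 1651). The others were assigned to F47B8.4, T13B5.9, Y48G8AR.8, Y39A1A.9, W01B6.8, fbxb-7, F54B11.4, F42A6.6, T28F4.1 and the divergent pair pde-6 and Y95B8A.6, which shared 1 summit. The summits of unk-1 and T28F4.1 lay inside the gene, upstream of an internal annotated 5' end. Of these 15 summits, 6 also lay in a coding exon. The summits assigned to inx-18, T13B5.9, W01B6.8 and F54B11.4 fell inside the neighbouring collagen genes col-102, col-40, col-2 and col-44. The GC content within 50 bp of the 15 summits ranged from 58.4% to 74.3%.

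Promoters held more of the summits than their share of the genome. Of the 2194 nuclear summits, 846 lay from 1000 bp upstream to 200 bp downstream of the 5' end of a protein-coding transcript (38.6%, 95% interval 36.5 to 40.6), against 26.1% of bases (exact binomial p = 2.68e-37). Coding exons outside promoter windows held 21.9% of summits against 18.9% of bases, and exons of noncoding genes held 4.33% against 2.15%. Introns were underrepresented, with 14.9% of summits against 27.8% of bases, as were 3' UTRs with 0.501% against 2.35% and intergenic DNA with 19.3% against 22.3%. These 5 classes differed from their share of bases at adjusted p values of 5.45e-04, 1.02e-09, 1.80e-45, 2.57e-11 and 7.57e-04, in the order given. The conservative list lacked 201 nuclear regions that passed the same IDR score, and 183 of them were intergenic. The low intergenic share therefore describes the list and not all regions past that score. The 10 summits in 5' UTRs did not pass the exact test (adjusted p = 0.736), although the share was above that of bases in each replicate's own list (exact adjusted p = 0.0263 in replicate 1 and 0.0210 in replicate 2). The 3' UTR share was 0.764% in the list of replicate 2, still below that of bases. Of the 846 promoter summits, 156 (18.4%) also lay in a coding exon. The median distance from a summit to the nearest protein-coding 5' end was 864 bp, and 33.5% of summits lay within 500 bp of one.

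**Figure D1:**
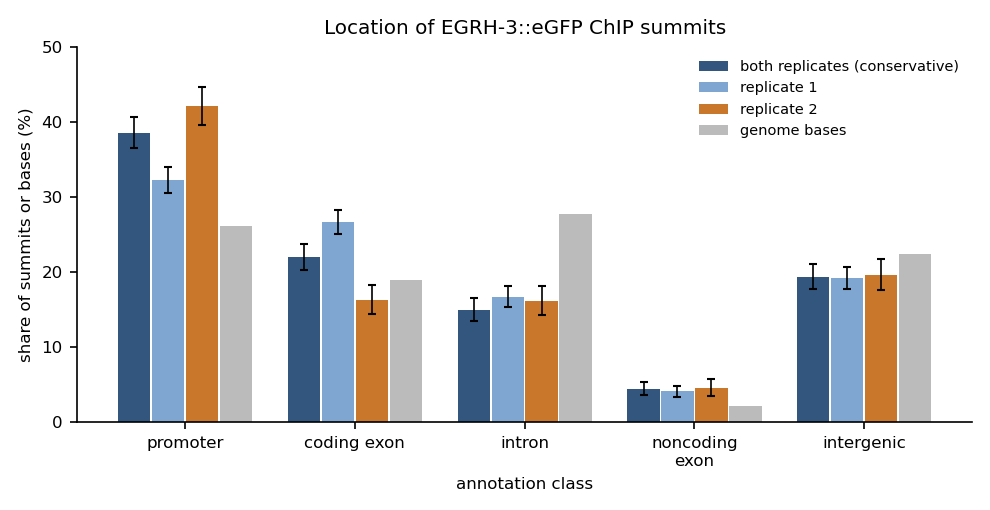
Share of summits in each annotation class (y axis, %) for the conservative list and for each replicate's own list, with exact 95% intervals over peaks, beside the share of genome bases in grey. Promoters held 38.6% of conservative summits against 26.1% of bases, and the coding exon share was 26.6% in replicate 1 and 16.2% in replicate 2.

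The replicates' own lists differed in where their summits lay. The promoter share was 32.3% in replicate 1 (30.6 to 34) and 42.1% in replicate 2 (39.5 to 44.7). The coding exon share was 26.6% in replicate 1, above the 18.9% of bases (adjusted p = 2.90e-23), and 16.2% in replicate 2, below it (adjusted p = 0.0120, exact binomial tests). Peaks found in replicate 1 and not in replicate 2 had 30% of summits in coding exons and a mean GC content of 58.1% (SD 8.0, 1695 peaks). Peaks found in replicate 2 and not in replicate 1 had 5.05% in coding exons, 53.0% in promoters and a mean GC content of 48.3% (SD 7.69, 317 peaks).

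In the conservative list, chromosomes I and III carried more peaks than their length and chromosomes V and X fewer. Chromosome I held 18.9% of peaks against 15% of bases (adjusted p = 4.79e-06, exact binomial test over 6 chromosomes) and chromosome III 16.7% against 13.7% (adjusted p = 1.62e-04). Chromosome V held 17% against 20.9% (adjusted p = 1.26e-05) and chromosome X 15.2% against 17.7% (adjusted p = 0.00310), also by exact tests. Chromosomes II and IV did not pass the exact test (adjusted p = 0.571 and 0.888). In the list of replicate 2 alone the X share was 16.7% and did not pass the exact test (adjusted p = 0.443). Of the 201 nuclear regions past the same IDR score but absent from the conservative list, 61 (30.3%) lay on chromosome X. The low X share therefore describes the list and not all regions past that score. On the autosomes, 27.4% of 1861 peaks lay in the central 33.3% of each chromosome (exact binomial p = 4.01e-08), and the arms held the rest.

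Genes of protein synthesis, protein folding and respiration had promoter summits more often than other genes. Of 39 gene lists chosen before the data were examined, 12 passed an adjusted p of 0.05 in Fisher's exact test, 7 above and 5 below the background of 971 bound genes among 19973. Among ribosomal protein genes, 23 of 81 were bound (odds ratio 7.92, 95% interval 4.64 to 13.1, Fisher's exact adjusted p = 6.09e-11). The strongest were rps-24 (chromosome IV, summit 385519, signal 538), rpl-3 (chromosome III, 3867581, signal 490) and rpl-15 (chromosome IV, 654918, signal 389). Among heat shock and DnaJ genes, 11 of 51 were bound (odds ratio 5.43, exact adjusted p = 3.50e-04), led by dnj-28 with a signal of 507, hsp-3, an endoplasmic reticulum chaperone, with 454, and hsp-1, a constitutive Hsp70, with 316. Among genes of mitochondrial respiration, 10 of 45 were bound (odds ratio 5.64, exact adjusted p = 4.63e-04), led by cox-5B at 193, atp-1 at 177 and atp-5 at 149. Among translation factors, 7 of 38 were bound (odds ratio 4.44, exact adjusted p = 0.00824), led by eef-1A.1 at 232, eif-2Bgamma at 178 and eef-1A.2 at 169. Among histone genes, 12 of 72 were bound (odds ratio 3.95, exact adjusted p = 0.00132), through 7 summits, as a summit can lie in more than 1 promoter window. The strongest were his-67 and his-68, which shared a summit on chromosome I at 9988984 (signal 132), and his-60, whose summit lay in the neighbouring his-59 (signal 115). In the list of replicate 1 alone, 5 respiration genes were bound and that list did not pass (odds ratio 2.37, exact adjusted p = 0.222), and in replicate 2 alone histone genes did not (odds ratio 2.90, exact adjusted p = 0.0519). Heat shock genes passed in both at lower odds ratios, 3.54 in replicate 1 and 3.59 in replicate 2. Histone genes also did not pass when each summit was given to the nearest gene alone (7 of 72, odds ratio 2.65, exact adjusted p = 0.0675) or with windows of 500 bp upstream (6 of 72, exact adjusted p = 0.0721). The heat shock, respiration, translation factor and histone lists did not pass at an IDR under 0.001, with 414 genes bound, or among peaks above the median signal, with 452 bound (exact adjusted p values from 0.121 to 0.708). At these settings the odds ratios were 4.05 and 3.70 for heat shock genes, 3.39 and 4.24 for respiration, 4.07 and 3.72 for translation factors, and 0 at both for histones.

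Heterochronic genes, which time the stages of larval development, were bound in 5 of 13 cases (odds ratio 12.3, 95% interval 3.16 to 42.7, Fisher's exact adjusted p = 0.00162). The strongest were mab-10 (signal 395), lin-66 (chromosome IV, summit 13887687, signal 304) and sea-2 (chromosome II, 3965856, signal 191, also in a coding exon of sea-2). mab-10 and lin-29 belonged to both this list and the EGR list. In replicate 2 alone 2 of the 13 were bound and the list did not pass (odds ratio 4.87, exact adjusted p = 0.222), while in replicate 1 alone the exact adjusted p was 0.00379. The list also did not pass at an IDR under 0.001 (2 of 13, odds ratio 8.63, exact adjusted p = 0.187). Against genes with a ranked region it did not pass either (5 of 10, odds ratio 5.78, exact adjusted p = 0.0725). In the larger peak list it passed at a lower odds ratio (4 of 13, 6.34, exact adjusted p = 0.0246).

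The 5 lists below the background were chemoreceptors, F-box, MATH and BTB genes, innate immunity effectors, detoxification enzymes, and neuropeptides and insulins. Chemoreceptor genes were bound in 15 of 1365 cases (1.10%, odds ratio 0.205, 95% interval 0.114 to 0.341, Fisher's exact adjusted p = 1.87e-13). By the same exact test, the corresponding counts were 6 of 412 for F-box, MATH and BTB genes (odds ratio 0.285, adjusted p = 0.00165), 6 of 334 for innate immunity effectors (odds ratio 0.354, adjusted p = 0.0228), 1 of 185 for detoxification enzymes (odds ratio 0.105, adjusted p = 0.00737) and 1 of 144 for neuropeptides and insulins (odds ratio 0.136, adjusted p = 0.0347). The strongest bound members were srh-246 at a signal of 387, sri-71 at 278 and sri-37 at 214 among chemoreceptors, fbxb-7 at 1068, fbxa-176 at 611 and fbxa-83 at 229 among F-box genes, and the lectin genes clec-123 at 155, clec-126 at 120 and clec-104 at 118. The single bound members of the last 2 lists were gst-27 at 174 and nlp-40 at 83.8. At an IDR under 0.001 neither had a promoter summit, and nlp-40 had none in the list of replicate 2 either. The detoxification list did not pass the exact test in either replicate's own list (odds ratio 0.309, adjusted p = 0.0880 in replicate 1 and 0.144, adjusted p = 0.0519 in replicate 2). In replicate 2 alone the odds ratio was 0.111 for chemoreceptors, 0.159 for immunity effectors and 0 for neuropeptides, all past the threshold. The F-box, detoxification and neuropeptide lists did not pass at an IDR under 0.001 (odds ratios 0.342, 0 and 0, exact adjusted p values from 0.199 to 0.257). Among peaks above the median signal these lists and immunity effectors did not pass (odds ratios 0.418, 0.233, 0 and 0.128, exact adjusted p values from 0.0631 to 0.441). With windows of 500 bp upstream the adjusted p was 0.153 for detoxification and 0.376 for neuropeptides, with windows of 2000 bp it was 0.0635 for detoxification, and with the nearest gene alone it was 0.133 for neuropeptides. With the background limited to the 6555 genes that had any ranked region in the promoter window, 4 lists passed the exact test, namely ribosomal proteins (adjusted p = 0.0129), EGR genes, heat shock genes and histones (adjusted p = 0.0341 each). Chemoreceptors then had an odds ratio of 1.09 (exact adjusted p = 1).

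The other 27 lists did not pass the threshold. Body-wall muscle genes came closest, with 5 of 36 bound (odds ratio 3.17, exact adjusted p = 0.0870), among them the myosin gene unc-54 at a signal of 171, and they passed in the larger peak list (adjusted p = 0.0246), in replicate 1 alone (0.0368), with windows of 2000 bp upstream (0.00469) and with the nearest gene alone (0.0446). They did not pass in replicate 2 alone (3 of 36, odds ratio 2.44, exact adjusted p = 0.319), at an IDR under 0.001 (0.476), above the median signal (0.477), with windows of 500 bp upstream (0.0721) or against genes with a ranked region (0.839). Regulatory genes included atf-6, a regulator of the unfolded protein response (signal 803), and hlh-30, the worm's TFEB (signal 663). Their lists had 11 of 126 members bound among zinc finger, GATA, T-box, forkhead, ETS, bZIP and SOX factors, 2 of 39 among bHLH genes, 13 of 274 among nuclear hormone receptors and 4 of 95 among homeobox genes. The counts were 2 of 17 for insulin-like signalling and stress regulators, which passed in replicate 2 alone with 4 of 17 (exact adjusted p = 0.0214) and with windows of 2000 bp upstream with 5 of 17 (0.0202), 3 of 29 for the cell cycle, 1 of 25 for the Wnt pathway, 0 of 19 for the EGF-Ras-MAPK pathway, 1 of 16 for the Notch pathway and 1 of 18 for the TGF-beta pathway. Tissue lists had 2 of 43 germline and oogenesis genes, 2 of 79 sperm genes, 0 of 22 somatic gonad genes, 1 of 26 intestinal genes, 0 of 31 epidermal genes, 2 of 28 pharyngeal genes, 0 of 26 pan-neuronal genes, 0 of 19 neurotransmitter genes and 1 of 21 vulval genes. Col collagens were bound in 6 of 156 cases (odds ratio 0.781), but with windows from 2000 bp upstream to 500 bp downstream, which reach into the gene, in 37 of 156 (odds ratio 3.84, exact adjusted p = 4.60e-09). The remaining counts were 4 of 85 hedgehog-related genes, 2 of 33 proteasome genes, 2 of 20 vacuolar ATPase genes, 3 of 59 actin and adhesion regulators, 2 of 77 lipid and yolk genes and 4 of 46 small RNA pathway genes. Adjusted p values of these lists ran from 0.0870 to 1, and the small lists leave wide intervals.

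**Figure D2:**
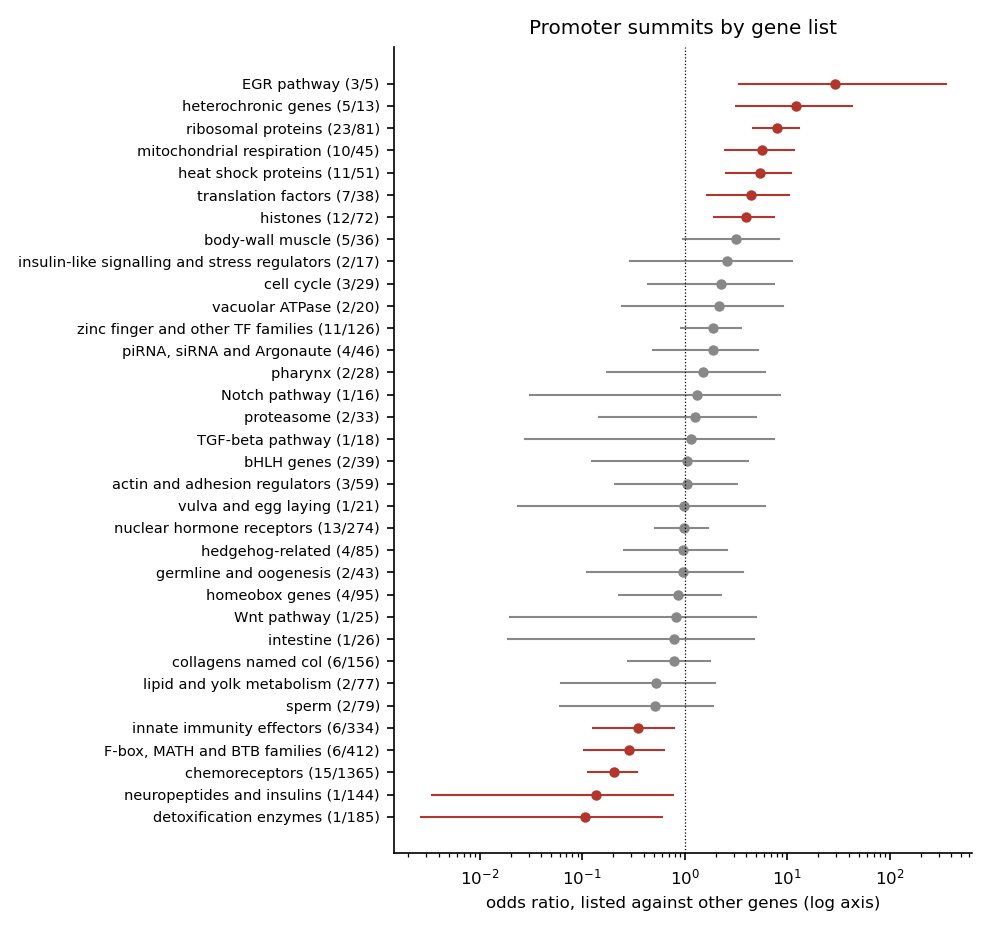
Odds ratio of carrying a promoter summit (x axis, log scale) for each gene list with at least 1 bound gene, with exact 95% intervals. Bound and total genes stand in parentheses, and red points mark lists with an adjusted p under 0.05, such as ribosomal proteins with 23 of 81.

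Collagen genes carried summits inside the gene more often than in the promoter. This comparison was chosen after the data were seen, because many strong summits lay in coding exons. Of the 156 genes named col, which encode mostly cuticle collagens, 98 had a summit between their annotated start and end (62.8%, 95% interval 54.7 to 70.4), against 834 of 19817 other protein-coding genes (4.21%, odds ratio 38.5, p = 6.67e-91 by Fisher's exact test). These genes took up 0.234% of the nuclear genome and held 134 summits, 6.11% of all, and 131 of those lay in a coding exon. The strongest were in col-102 (chromosome IV, summit 605629, signal 2134), col-50 (chromosome I, 3651464, signal 1564), col-51 (chromosome I, 3655085, signal 1432) and col-40 (chromosome II, 1105474, signal 1331). The share was 79.5% in the list of replicate 1 and 46.2% in that of replicate 2. The median GC content within 50 bp of the 134 summits was 63.9%. Among genes whose most GC-rich coding stretch had 66.3% to 70.3% GC, 61 of 78 col genes (78.2%) and 175 of 320 other genes (54.7%) held a summit.

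**Figure D3:**
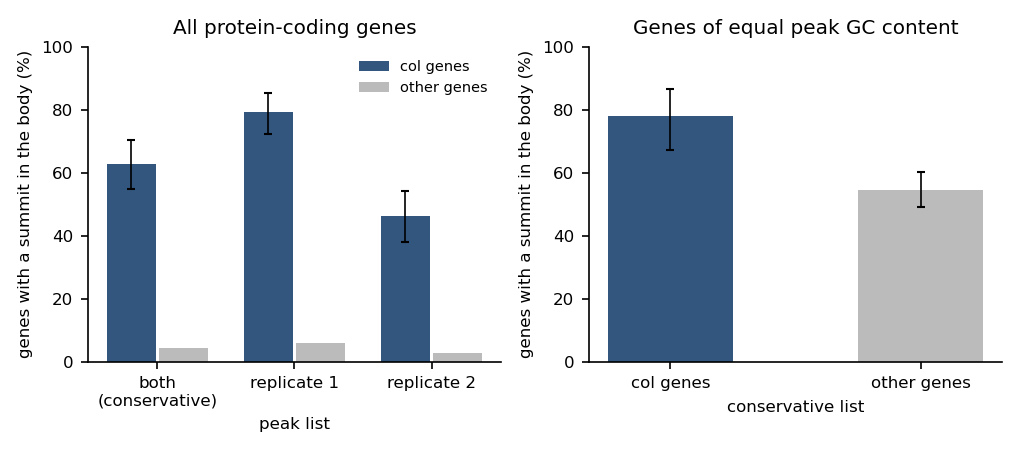
Share of genes with a summit inside the gene (y axis, %). Left, col genes (with exact 95% intervals) and all other protein-coding genes in the conservative list and in each replicate's own list, with 62.8% against 4.21% in the conservative list. Right, the same share in the conservative list among genes whose most GC-rich coding stretch had 66.3% to 70.3% GC, 78.2% for col genes and 54.7% for others.

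Summits were GC-rich. This property was examined after the data were seen, while GTGGGYG, the 4 other patterns and the test of all 6-mers were planned. The mean GC content within 50 bp of the summit was 56.0% (SD 9.39, 2194 summits), against 39.5% (SD 11.1) in windows of the same width centred 300 bp to either side and 35.4% in the nuclear genome. Coding exon summits had the highest mean, 61.4% (SD 5.51), and promoter summits had 55.2% (SD 8.42). The core shared by EGR binding sites of other animals, GTGGGYG, was present within 50 bp of 71 of 2192 summits (3.24%), against 1.32% of left and 2.14% of right flanks. The ratio to the mean of the flanks was 1.87 (95% interval 1.33 to 2.62), with exact McNemar p = 2.15e-05 and 0.0338 for the left and right side. The full site GCGTGGGCG was in 0 summit windows. Among summits in promoter windows the ratio was 1.38 and passed the exact test on neither side (p = 0.324 and 0.522).

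Other patterns were also enriched, and differences between their ratios and that of the core were not tested. GGGCGG, whose bases GGGCG also occur in one form of the core, was found at 9.58% of summits, 3.33 times the flanks, GAGAGA at 19.8%, 2.84 times, and the E-box CACGTG at 3.15%, 2.26 times (95% interval 1.58 to 3.25). Runs of TTTTTT were found at 10.9% of summits against 33.9% and 36.7% of flanks. Of 2080 strand-collapsed 6-mers, 703 were more and 721 less frequent at summits than in flanks at an adjusted p under 0.05 by exact binomial tests. The largest ratios among 6-mers in at least 50 summit windows belonged to GCGCGC (10.1), CGCGCG (9.45) and CGGCCG (7.73). The median ratio rose with each G or C in the 6-mer, from 0.180 with none to 0.991 with 3 and 4.13 with 6.

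**Figure D4:**
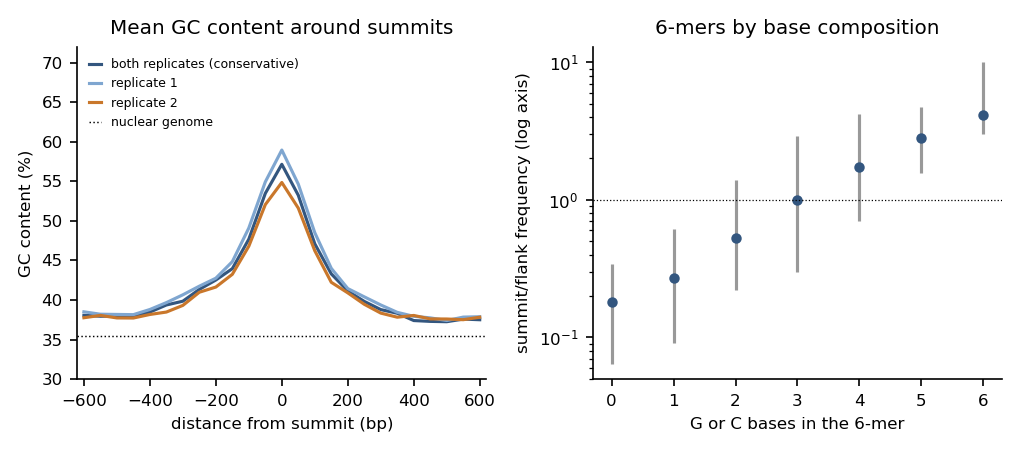
Left, mean GC content (y axis, %) in 51-bp windows by distance from the summit (x axis, bp) for the conservative list and each replicate's list, with the nuclear genome's 35.4% dotted. Right, ratio of summit to flank frequency (log axis) of 6-mers by their number of G or C bases, with the median as a point and the full range as a line, rising from 0.180 to 4.13.

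Short noncoding RNA genes lay close to many summits. They were examined as a planned check for background, as very highly transcribed short genes can pull down chromatin with any GFP antibody. Lists from untagged worms were not analysed here, so these summits could not be told from such background. Of the 2194 summits, 214 (9.75%, 95% interval 8.54 to 11.1) lay within 200 bp of a tRNA, snRNA, snoRNA, rRNA or miRNA gene, against 0.650% of bases (exact binomial p = 2.49e-171). Transfer RNA genes accounted for 120 summits (5.47% against 0.272% of bases, exact adjusted p = 1.47e-109), and 134 of the 612 tRNA genes had a summit within that distance. Summits near snoRNA genes numbered 63 (2.87% against 0.182%, exact adjusted p = 7.84e-52), near snRNA genes 23 (1.05% against 0.0655%, adjusted p = 6.25e-20) and near miRNA genes 8 (0.365% against 0.118%, adjusted p = 0.00637). No summit lay near the 20 rRNA genes, which allows a share of up to 0.168%. That limit is above their 0.0170% of bases, so a low share could not be shown. Within 200 bp of any of these genes lay 5.79% of summits in the list of replicate 1 and 14.5% in that of replicate 2. The tRNA share was 2.88% in replicate 1, 9.17% in replicate 2, 2.37% among peaks above the median signal and 2.66% at an IDR under 0.001, the snRNA share was 0.491% in replicate 1, and the miRNA share was 0.556% in replicate 2, all above the share of bases by exact tests. The miRNA class did not pass among peaks above the median signal (exact adjusted p = 0.0526) or for summits inside the gene (2 summits, exact adjusted p = 0.130).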

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

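Signal outside the nuclear peaks of the conservative list was found in 2 places. In the ranked list that pairs the replicates, 201 nuclear regions passed the same IDR score as the conservative list and were absent from it. They had a median signal of 399 and a highest of 12618, and all of the 10 strongest nuclear regions of that ranked list were among them, the first on chromosome IV from 2828502 to 2829600, the next on chromosome X from 5056222 to 5057256. Grouped within 20000 bp they formed 64 clusters, 91.0% were intergenic and 30.3% lay on chromosome X. Soft-masked repeat sequence made up a mean of 92.6% of their bases, against 26.3% in the conservative peaks and 35.7% of the nuclear genome.

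Mitochondrial DNA carried 24 peaks of the conservative list, in 19 intervals, with a median signal of 375 and a highest of 2935.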

How the results depend on the processing

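The IDR limit under 0.001, promoter windows without coding exons and the alternatives for summits inside collagen genes were chosen after the data were seen. Promoter share, the pooled share near short noncoding RNA genes and the share of col genes with a summit inside kept their direction and passed their tests under every alternative run for them, with promoter shares of 31.4% without coding exons and 32.3% to 42.1% in the replicates' own lists. The planned IDR limit of 0.01 removed no nuclear peak, so it tested nothing. The IDR limit under 0.001 left 1038 peaks, 4 gene lists past the threshold, a GTGGGYG ratio of 1.81 (right flank exact p = 0.144) and a histone odds ratio of 0. The part of the list above the median signal left 4 lists, a GTGGGYG ratio of 2.13 (right flank exact p = 0.0534) and a histone odds ratio of 0. Both settings keep fewer peaks and bound genes. The background of genes with a ranked region left 4 lists and a chemoreceptor odds ratio of 1.09, and gave no finite odds ratio for EGR genes, as all 3 that remained were bound. The GTGGGYG ratio was 1.38 in promoter windows, where 846 peaks remained. It passed on both sides in the larger list (2.40), in replicate 1 (2.64) and replicate 2 (2.29) alone, with flanks at 600 bp (2.41), with windows of 100 bp each side (1.79) and at peak midpoints (2.03). GCGTGGGCG, with a ratio of 0, was in 0 summit windows and too rare in the flanks to show a difference. Replicate overlap was 58.9% with 50% of both peaks required, 71.1% for summits within 100 bp and 56.8% for lists of equal length, and rho was 0.573 over all ranked peaks. The causes of these shifts were not tested beyond the number of peaks left. The list of replicate 2 held 1463 peaks with an X share of 16.7%, that of replicate 1 2868 with 15.6%, and each gave 10 lists past the threshold, 9 of them among the 12. Leaving out the IDR limit of 0.01, the 12 lists' odds ratios had 107 alternative values, those above included, of which 71 kept direction and side of the threshold, 33 kept direction only and 3 reversed. On the same terms, 36 of 264 alternatives changed whether a named gene had a promoter summit. Sequencing depth is unknown, so its effect on list length could not be weighed.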

Other observations

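The tests in this part were chosen after the patterns had been seen. For the 6 explanations weighed, the outcomes for and against were written before the deciding value was computed, but the GTGGGYG ratio, the GC trend of the 6-mers and the GC content of peaks found in a single replicate had been seen by then. Summits inside the gene, between its annotated start and end, also set other gene lists apart, with 14 of 39 past the threshold, 9 above the background and 5 below. Heterochronic genes held one in 7 of 13 cases (odds ratio 24.0, adjusted p = 6.16e-06 by Fisher's exact test over 39 lists). The strongest were in introns of lin-42, the worm's Period homolog (chromosome II, summit 1238053, signal 1110), and daf-12, a nuclear hormone receptor (chromosome X, 10637488, signal 454), followed by a coding exon of sea-2 (signal 258) and an intron of lin-14 (chromosome X, 11473427, signal 242). Hedgehog-related genes held one in 16 of 85 cases (odds ratio 4.80, exact adjusted p = 1.32e-05), led by grl-25 with a signal of 1655 and grl-23 with 779, both in coding exons. Epidermal genes, with 6 of 31 (odds ratio 4.93, exact adjusted p = 0.0107), included sqt-3, dpy-13, lon-3 and dpy-17, which encode cuticle collagens outside the col names. Body-wall muscle genes had 7 of 36 (exact adjusted p = 0.00640) and pan-neuronal genes 5 of 26 (adjusted p = 0.0206), although no pan-neuronal gene had a promoter summit. Ribosomal proteins (11 of 81), respiration genes (7 of 45), insulin-like signalling (4 of 17) and col genes were the others above. The 5 below were those low in promoter summits, with 9 of 1365 chemoreceptors (odds ratio 0.127), 1 of 412 F-box, MATH and BTB genes (0.0487), 2 of 334 immunity effectors (0.121), 1 of 185 detoxification enzymes (0.110) and 1 of 144 neuropeptides and insulins (0.142). Some summits counted for 2 lists. The respiration gene ucr-2.2 shared its summit with col-41, and the detoxification gene ugt-65 shared its summit with col-130. Long genes offer more room for a summit, and neither gene length nor GC content was taken into account in these list tests. The tests were run on the conservative list alone.

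The replicates ranked GC-rich peaks differently. Across 2070 conservative peaks, the ratio of the replicate 1 to the replicate 2 signal rose with GC content within 50 bp of the summit (Spearman rho 0.637, across peaks). Across 4 groups of peaks ordered by GC, the median ratio was 1.07 in the lowest and 3.03 in the highest. Promoter summits of ribosomal protein genes had a median GC content of 52.5% and a median ratio of 1.04, while summits inside col genes had 63.9% and 2.95. The 3 promoter summits of EGR genes had medians of 66.3% and 4.57. The egrh-2 summit among them had 54.5% GC, with a signal of 45.7 in replicate 1 and 46.9 in replicate 2. A shared scale of the 2 lists is not assumed here, and a constant factor between them would leave the rho as it is.

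The first pattern weighed was the frequency of summits inside col genes. GC content goes with much of it: among genes not named col, a summit was present in 1.08% of those whose most GC-rich coding stretch had under 50% GC and in 51.6% of those at 65% or more. Stratified by that measure, the odds ratio of col genes fell from 38.5 to 2.73 (95% interval 1.79 to 4.18), which argues against this measure of GC as the whole cause and leaves it as a candidate explanation for most of the excess. For shared reads between paralogs, repeated 36-mers were counted in windows around the strongest summit of each of the 98 genes. The median share of repeated 36-mers was 0% (upper quartile 16.1%, highest 100%). No repeat was found at 53 of the 98 summits, which argues against shared reads for those. For the others, the median cannot exclude them. What accounts for the remainder, background enrichment included, stays open, and no biological explanation was tested, because the series has 1 group.

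The second pattern was the excess of GTGGGYG at summits. Among 882 pairs of 7-mers made of the same bases in another order, the ratio of 1.87 stood at percentile 9.41, below the median of 2.55, so base composition alone may account for the excess. Location in promoters is argued against, because the ratio was 2.23 (95% interval 1.45 to 3.43) at the 1346 summits outside promoter windows. The data therefore hold no enrichment of the EGR core beyond what GC-rich sequence brings in this test, and whether EGRH-3 recognises that core was not tested. No biological explanation was tested.

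The third pattern was the lower promoter share of replicate 1, 32.3% against 42.1%. A longer list in replicate 1 is argued against, since its strongest 1439 peaks, as many as replicate 2 had, also had a promoter share of 32.3% (95% interval 29.9 to 34.8). Stratified by summit GC, the odds ratio of promoter location in replicate 2 against replicate 1 fell from 1.53 to 1.40. Its 95% interval of 1.22 to 1.60 argues against summit GC as the whole cause of the difference between these 2 lists. That interval covers counting error over peaks, many of which overlap between the lists, and not the spread between libraries. Sequencing depth and differences between the 2 libraries stay open, and no biological explanation was tested.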
